A study of Homo sapiens with 4 samples.

How the data were processed

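Total RNA from cultured human lung adenocarcinoma cells was measured on 4 one-colour Affymetrix expression arrays, 1 array for each of 4 groups. The cells were CL1-0 carrying an empty vector, CL1-0 carrying a PSAT1 expression vector, CL1-5 carrying a non-silencing short hairpin and CL1-5 carrying a hairpin against PSAT1. Per the labels, all were stably transduced and kept under puromycin for 2 weeks, and biotinylated cRNA was made from 6 ug of total RNA. The deposited values are linear probe set intensity, 1 value per probe set and array, and the authors used MAS5, per the submitters' processing notes. Neither its version nor a scaling target is given in the sources used here, and the table used here carries no detection calls.

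The table held 54675 probe sets, of which 62 were control probe sets. The medians were 53.2 and 53.2 on the vector and PSAT1 arrays of CL1-0, and 45.4 and 46.0 on the non-silencing and hairpin arrays of CL1-5. Identical values at the same probe set occurred at 1260 probe sets between the CL1-0 arrays and at 1749 between the CL1-5 arrays, and at 0 between arrays of different lines. In the same order, the 75th percentiles were 252 and 272 in CL1-0 and 177 and 173 in CL1-5, and means trimmed at both ends were 329.5 and 327.8 in CL1-0 and 211.8 and 210.7 in CL1-5. All of these differed more between the lines than within them, and the 75th percentiles of CL1-0 also differed from each other. Whether the lines were normalized separately is not given in the sources used here, so every level set across lines is subject to that. Equality here means no difference in any deposited digit.

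Signals were set to a floor where below it and then log2 transformed. The floor, 49.0, was the pooled median (the 50th percentile) of all non-control probe sets on the 4 arrays and stands in for detection calls. A gene counted as measured in a pair of arrays if at least 1 of them was above the floor. With the other at the floor its fold is a lower bound, computed against the floor and written "at least". Genes with both arrays at the floor were not measured in that pair.

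Probe sets were named from the platform annotation, which gave 1 gene symbol to 41097 probe sets, several to 1801 and listed no gene for 11777. Of those with 1 gene, 41043 were found in a human reference gene table that updated their symbols. Probe sets with several symbols named no gene. Genes of the Y chromosome and of X inactivation were left out, which removed 59 probe sets. A gene was represented by its probe set with the highest mean floored log2 signal over the 4 arrays. This left 19740 genes, 10511 of them with more than 1 probe set. Of the 533 members of the gene lists, 43 had no named probe set and were not analysed here. The build of the platform annotation is not given in the sources used here, and no coordinates were used.

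With 1 array per group there was no replicate, so no test, p-value or standard error was computed. In the text "higher", "rose", "lower" and "fell" mean a difference of 2-fold or more between 2 arrays, a rule of size alone. The number of arrays limits the precision, and a difference between 2 arrays covers culture, selection and labelling as well as the construct. The SD of the log2 ratio between probe sets of the same gene was 0.289 in the CL1-0 pair, 0.175 in the CL1-5 pair and 0.514 between the lines. The SD of log2 ratios across measured genes, estimated from the median absolute deviation, was 0.33, 0.19 and 0.71 in the same order. Neither replaces a replicate.

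The comparisons were CL1-0 with PSAT1 against CL1-0 with vector, CL1-5 with the PSAT1 hairpin against CL1-5 with the non-silencing hairpin, the control arrays of the lines against each other, and the manipulations against each other across genes. Each of 21 gene lists was described by its count of 2-fold changes, its median log2 ratio and the percentile of that median among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. The percentile describes these arrays only. A median was given where more than 2 members were measured. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule took, per pair of arrays, PSAT1, the 10 largest rises and 10 largest falls among genes whose brighter array reached the pooled 75th percentile (signal 212.6) and whose other probe sets above the floor did not go the other way. It also took up to 10 genes per direction moving opposite ways in the manipulations under the same conditions, up to 4 measured members of each list with the largest change, and a few fixed members of the serine and interferon gamma lists. Genes outside this rule were named only where a count was 5 or fewer, among the genes moving opposite ways, or in the closing part, after their values were seen.

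The alternatives were quantile normalization of all 4 arrays, centring each array on the median of probe sets above the floor on all arrays, a floor at the pooled 25th or 65th percentile, the mean over a gene's probe sets, leaving out probe sets whose design allows hits on several transcripts, 1.5-fold and 3-fold rules, and a rule that all probe sets of a gene share a sign. A further 6 gene lists were chosen after the data were seen.

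Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The counting and list steps were tested on simulated arrays of all 19740 genes with the spread across genes given above, shared equally between the arrays of a pair. The simulated noise was normal with the same SD at every signal level, so the counts do not give the false calls of the real arrays. The changed genes were drawn only from those whose mean signal was more than 2-fold above the floor. Recovery of changes nearer the floor was therefore not tested. With the spread of the CL1-0 pair, 93 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were called, as were 28 of 12886 unchanged measured genes. With the spread of the CL1-5 pair these were 99, 98 and 0 of 12545. Of 100 unchanged lists, 5 lay outside the central 95% of random lists in the first case and 3 in the second.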

Results

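CL1-0 and CL1-5 are human lung adenocarcinoma lines of one origin. CL1-5 was derived from CL1-0 by selection for invasiveness and is the more invasive of the pair. PSAT1, phosphoserine aminotransferase, carries out the transamination step of serine synthesis and yields alpha-ketoglutarate from glutamate. Per the labels, a PSAT1 expression vector was put into CL1-0 and a hairpin against PSAT1 into CL1-5, and the series asked how gene expression differed from each line's control. There were 4 groups with 1 array each and no replicates. The 4 arrays had 52.0%, 51.7%, 48.0% and 48.3% of probe sets above the floor, in the order CL1-0 vector, CL1-0 PSAT1, CL1-5 non-silencing and CL1-5 hairpin. Ratios of 3' to 5' control probe sets of GAPDH, a check of RNA integrity, ran from 1.07 to 1.10, and those of ACTB were 1.18, 1.22, 1.34 and 1.38 in the same order. Control probe sets of 28S ribosomal RNA read 5445, 3546, 8146 and 5351 in that order, and those of 18S ribosomal RNA read 3721, 2946, 9937 and 8140. Log2 signals correlated with Pearson r = 0.986 within CL1-0, 0.994 within CL1-5 and 0.931 between the control arrays of the lines, across probe sets.

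The targeted gene was read first, since it checks the labels. PSAT1 signal was far lower on the hairpin array of CL1-5 and only slightly above the control on the PSAT1 array of CL1-0. In CL1-5, the brighter of the 2 PSAT1 probe sets read 143 with the hairpin against 1760 with the non-silencing control, a 12.3-fold fall. The dimmer one read 107 against 384, a 3.58-fold fall. Both falls exceeded those of all 500 genes nearest in signal. In CL1-0, the same probe sets read 5494 against 4214 (log2 ratio 0.38, 1.30-fold) and 1617 against 1509 (0.10, 1.07-fold). Among the 500 genes nearest in signal, these ratios lay at the 94th and the 61.8th percentile. Neither reached 2-fold, and the positions of the probes relative to the introduced sequence are not known here, so these arrays do not measure how much PSAT1 the vector added.

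**Figure D1:**
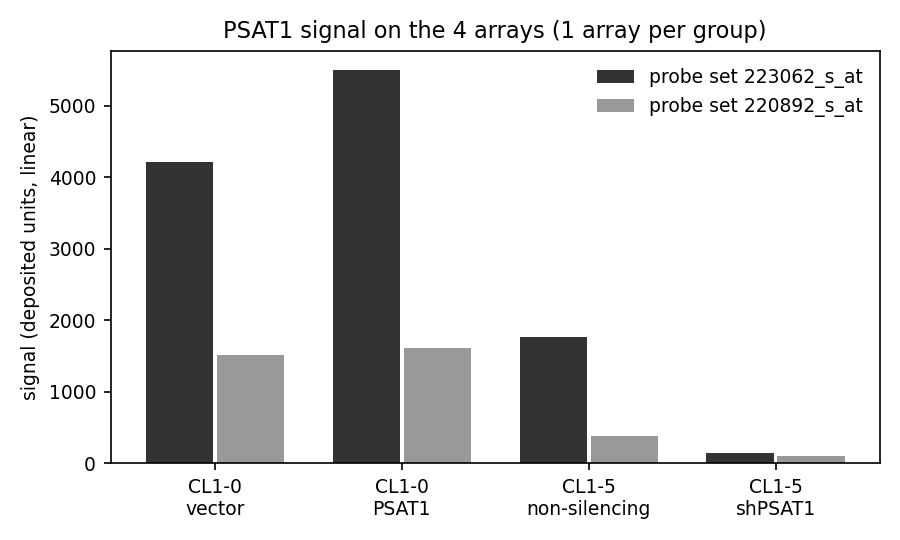
Signal in deposited linear units (vertical axis) of the 2 PSAT1 probe sets on each of the 4 arrays, 1 array per group, so no error is drawn. In CL1-5 the dark bar drops from 1760 to 143 with the hairpin, and in CL1-0 it goes from 4214 with the empty vector to 5494 with the PSAT1 construct.

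In CL1-0 with PSAT1, genes of the type I interferon response fell, many of them to the floor, while 8 of 27 genes of the amino acid response rose (6 under median centring). IFIT1, an interferon-induced RNA-binding antiviral protein, read 24.1 with PSAT1 against 8422 with vector, at least 172-fold lower. IFIT2 was at least 46.4-fold lower, RSAD2 (viperin) at least 33.4-fold and IFIT3 at least 27.1-fold. OASL was 28.6-fold lower. The chemokine CCL5 fell at least 41.9-fold. DDIT4 and DDIT3, both stress-induced and downstream of the transcription factor ATF4, rose 3.50-fold and 3.46-fold.

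Over all genes of the CL1-0 pair, 13187 were measured, 337 were higher with PSAT1 and 133 lower, so that 71.7% of the 470 differences were rises. Quantile normalization gave 215 and 133 (61.8% rises), and median centring 245 and 143 (63.1%). At 3-fold or more the excess of rises nearly vanished, with 61 higher and 53 lower (53.5% rises). Probe sets of the same gene had opposite signs for 36 of the 470, and 84 rested on a bound. The 10 largest rises were FLRT3 (at least 31.6-fold), a membrane protein of cell adhesion, the fibrillar collagen COL11A1 (at least 22.3-fold), the peptide hormone APELA (at least 14.99-fold), the retinoic acid hydroxylase CYP26A1 (9.23-fold), CCDC50 (8.02-fold), the long noncoding RNA UCA1 (at least 7.92-fold), MATN2 (at least 7.62-fold), the transcription factor OLIG1 (at least 7.55-fold), MDFIC (at least 7.46-fold) and the metalloproteinase inhibitor TIMP1 (7.32-fold, 2028 against 277). Besides the 6 genes already given, the 10 largest falls held the transcription factor KLF4 (at least 30.3-fold), the glucagon gene GCG (at least 24.6-fold), the matrix protein periostin, POSTN (18.3-fold), and IFI44 (at least 15.1-fold).

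Of the 34 type I interferon genes with a named probe set, 22 were measured in the CL1-0 pair. Of these, 14 were lower with PSAT1 and 0 were higher. Their median log2 ratio was -1.79, below all 10000 random lists, and 20 of 22 ratios were negative. The exceptions were EIF2AK2 (1242 with PSAT1, 888 with vector) and BST2 (78.4 and 70.9). The array with vector had 22 of the 34 above the floor and the array with PSAT1 had 15. With the floor at the 25th percentile the median was -0.52, since 31 members then counted as measured, and 14 were again lower. The list of interferon gamma and IRF1 genes had 17 measured members and 1 fall, the chemokine CXCL10 (at least 5.45-fold), with a median of -0.29 at the 0.04th percentile. IRF1 itself read 130 against 207 (log2 ratio -0.68), TAP1 380.0 against 576 and PSMB9 238 against 357, all under 2-fold. The receptor chains IFNGR1 (-0.11) and IFNGR2 (0.21) moved less. Antigen presentation genes had a median of -0.10 (23.8th percentile), with B2M at 9582 against 15208 and 1 rise, HLA-DMA (2.02-fold), which was under 2-fold with both other scalings and the 65th percentile floor.

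The amino acid response list, which holds targets of ATF4, had 8 of 27 measured members higher and 0 lower, with a median of 0.44 above all random lists. Its largest rises were DDIT4 (5101 against 1458), DDIT3 (1922 against 555), the lipoprotein receptor VLDLR (3.32-fold) and JDP2 (2.95-fold). The serine synthesis and one-carbon list as a whole did not stand apart in this way. None of its 18 measured members reached 2-fold, and its median was -0.05 (44.8th percentile). Its synthesis enzymes PHGDH and PSPH had log2 ratios of 0.34 and 0.33, not far below the amino acid response median of 0.44. SHMT2 had -0.21. GLDC, which cleaves glycine in mitochondria, had the largest ratio of the serine and one-carbon list, -0.60. Among glutamine, transaminase and TCA cycle genes (24 measured, median -0.03, 50.1th percentile) the 1 change was the mitochondrial isocitrate dehydrogenase IDH2, 2.18-fold higher. Glutathione and NRF2 targets had a median of -0.28 at the 0.05th percentile and 1 fall among 18, haem oxygenase HMOX1 (1010 against 2371, 2.35-fold). Glycolysis and hypoxia genes (26 measured, 22.6th percentile) and cholesterol and fatty acid synthesis genes (20 measured, 59.2th percentile) had no 2-fold change and medians of -0.06 and 0.04.

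Cell cycle genes shifted by small amounts in opposite directions. G2/M and mitosis genes had positive ratios in 25 of 27 members, with a median of 0.27 above all random lists and none at 2-fold, and the exceptions were PLK1 and MKI67. G1/S and DNA replication genes had a median of -0.19 (0.88th percentile) and 2 falls among 25, CDC25A (2.25-fold) and ORC1 (2.08-fold). That median lay inside the central 95% of random lists under quantile normalization (2.57th percentile) and with the mean over probe sets (3.48th). The list of p53 targets, genes of growth arrest, apoptosis and DNA repair, had a median of 0.25 (99.4th percentile), which was at the 96.4th with the 25th percentile floor and the 95.95th without multi-transcript probe sets. In it the stress cytokine GDF15 rose 5.95-fold, TP53INP1 rose 3.61-fold and PMAIP1, a pro-apoptotic protein, fell 2.74-fold. Heat shock and unfolded protein genes had a median of -0.17 (1.29th percentile) with 1 fall among 24, DNAJB1 (2.16-fold).

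Among genes of cell identity in CL1-0, the epithelial list had a median of -0.25 over 19 genes (0.58th percentile) and 2 falls, the desmosomal cadherin DSG2 (at least 9.06-fold) and CLDN4 (at least 2.29-fold). CLDN4 was under 2-fold with centring, the 65th percentile floor and the mean over probe sets. Under quantile normalization that median lay at the 8.39th percentile, under median centring at the 5.36th, and with the 65th percentile floor, the mean over probe sets and no multi-transcript probe sets at the 4.92th, 4.90th and 3.16th. Mesenchymal genes (16 measured, median -0.14, 12.4th percentile) held falls of ZEB2 (at least 3.72-fold), TWIST1 (2.42-fold) and TWIST2 (2.06-fold) and a rise of FOXC2 (at least 3.18-fold). The mesenchymal median was -0.35 (0.25th percentile) without multi-transcript probe sets but -0.06 (52.5th) under centring and -0.10 (42.3th) with the 25th percentile floor, and with the 65th percentile floor TWIST1 was the 1 change left. Matrix proteolysis and adhesion genes (22 measured, median -0.01, 65.5th percentile) held rises of TIMP1 and of TIMP2 (2.24-fold, under 2-fold with the mean over probe sets). Inflammatory and NF-kB genes had a median of -0.22 (3.93th percentile) over 15, with CCL5 the 1 fall. That median lay outside the central 95% under both other scalings (0.97th and 0.98th percentile), the 65th percentile floor (0.49th) and the mean over probe sets (1.99th). Wnt targets (12 measured, median 0.01, 62.4th percentile) held 1 fall, the Wnt antagonist DKK1 (63.9 against 328, 5.13-fold). Fibroblast markers (5 measured, median -0.33, 3.21th percentile) held 2 falls, POSTN and COL3A1 (at least 6.37-fold). The fibroblast median was -1.33 over 4 genes under median centring and -1.62 over 3 with the 65th percentile floor, both below all random lists, and lay at the 1.93th percentile under quantile normalization the 1.94th with the mean over probe sets and the 11.4th with the 25th percentile floor. Alveolar type II markers (10 measured, median 0.02, 59.4th percentile) and immune and endothelial markers (5 measured, median -0.24, 6.44th percentile, 1.59th under quantile normalization and 82.6th with the 25th percentile floor) had no 2-fold change.

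In CL1-5 with the PSAT1 hairpin, interferon-induced genes rose, and PSAT1 showed the largest fall. IFI27 read 1431 with the hairpin against 94.4 with the non-silencing control, a 15.2-fold rise. The antiviral GTPase MX1 rose 4.47-fold, RSAD2 3.55-fold, CMPK2 3.52-fold and the RNA sensor IFIH1 3.25-fold. S100A4, a calcium-binding protein of motile cells, fell 5.01-fold (380.4 against 1904), and the BMP antagonist NOG fell 9.79-fold.

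The CL1-5 pair held far fewer differences than the CL1-0 pair, with 51 genes higher and 54 lower among 12821 measured. Of these 105, 10 rested on a bound and 1 had probe sets of opposite sign. The SD between probe sets of the same gene was also smaller in CL1-5 (0.175 against 0.289 in CL1-0). The counts of the pairs therefore do not compare the sizes of their responses. The other genes among the 10 largest rises were the zinc exporter SLC30A1 (3.52-fold), IFITM1 (2.94-fold), TCEAL2 (2.93-fold), the redox regulator TXNIP (2.91-fold) and the immunoproteasome subunit PSMB8 (2.90-fold). The other large falls were DOCK4 (8.22-fold), the acetylcholine receptor subunit CHRNA9 (at least 7.68-fold), ECSCR (4.07-fold), the collagen COL6A3 (3.65-fold), the immediate early gene EGR1 (3.57-fold), NRCAM (3.42-fold) and the Notch target HEY1 (2.97-fold).

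All 30 measured type I interferon genes had positive ratios in CL1-5, and 16 were 2-fold higher. The median of 1.12 lay above all random lists. The interferon gamma and IRF1 list had 4 rises among 22 measured members, PSMB8, PSMB9 (2.69-fold), the inflammatory caspase CASP4 (2.02-fold) and the peptide transporter TAP1 (2.02-fold). Its median was 0.12, at the 97.4th percentile, with the 97.8th under quantile normalization, the 73.5th under centring and the 99.4th with the mean over probe sets, and 0.05 at the 68.2th percentile without multi-transcript probe sets. IRF1 read 127 against 122 (log2 ratio 0.05), with its probe sets of opposite sign, and IFNGR1 and IFNGR2 had ratios of 0.19 and -0.23. Antigen presentation genes had positive ratios in 14 of 15 members, with ERAP1 the exception, and a median of 0.39 above all random lists. HLA-DPA1 rose at least 2.12-fold, but under 2-fold with the 65th percentile floor and the mean over probe sets, while HLA-B (7271 against 3861) and HLA-C (7471 against 4267) stayed under 2-fold. HLA genes share sequence, and without multi-transcript probe sets the median was 0.11 at the 89.2th percentile.

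**Figure D2:**
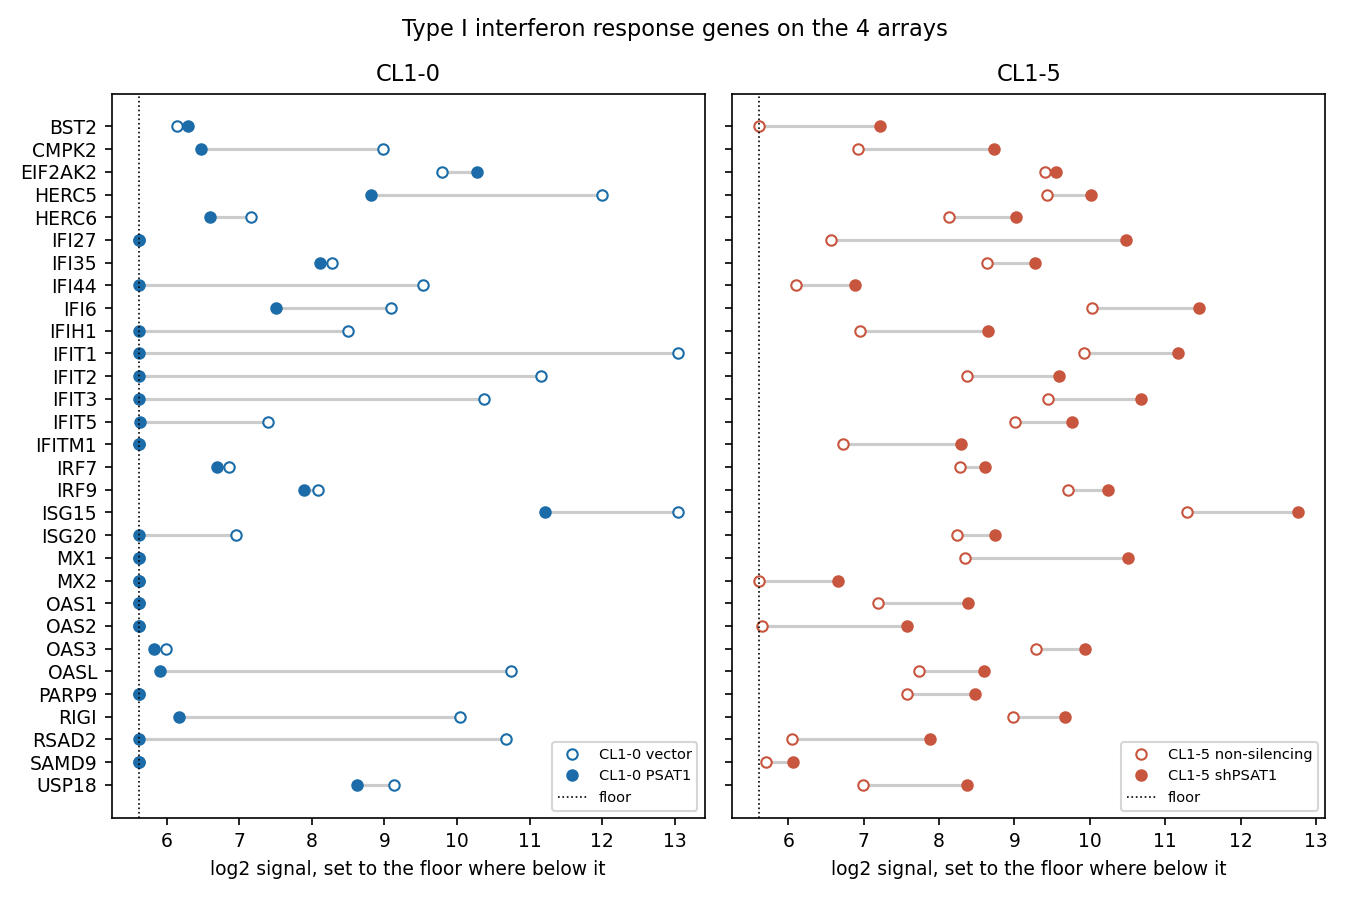
Log2 signal (horizontal axis, set to the floor where below it) of the type I interferon list genes above the floor on at least 1 of the 4 arrays, with open circles for controls and filled circles for the manipulated arrays, 1 array per group. In CL1-0, IFIT1 goes from 8422 to below the floor, and in CL1-5 it goes from 969 to 2313.

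Serine synthesis and one-carbon genes had no 2-fold change among 17 measured members in CL1-5 apart from PSAT1, which is not in the list. Their median was 0.04 (70.8th percentile), but 0.15 (99.8th) with the mean over probe sets and 0.16 (99.2th) without multi-transcript probe sets. PHGDH, PSPH and SHMT2 had log2 ratios of 0.34, 0.04 and 0.00. The amino acid response list had 0 changes among 27 and a median of -0.07 (5.27th percentile), with VLDLR at -0.97. Glutamine, transaminase and TCA cycle genes (24 measured, median -0.02, 25.6th percentile) and cholesterol and fatty acid genes (20 measured, median 0.06, 86.0th percentile) had none. Glutathione and NRF2 targets had 1 fall among 20, AKR1C1 (2.10-fold, under 2-fold with the mean over probe sets), and a median of -0.04 (9.70th percentile), which was -0.18 and below all random lists with the mean over probe sets. The glycolysis and hypoxia list had a median of -0.15, below all random lists, with no member at 2-fold and its largest ratio in NDRG1 (2063 against 3345, -0.70). Heat shock and unfolded protein genes had no change among 24 and a median of -0.04 (14.1th percentile).

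G1/S and DNA replication genes of CL1-5 had positive ratios in 23 of 25 members (exceptions RRM1 and POLA1), with a median of 0.36 above all random lists and the largest ratios in the cyclins CCNE1 (774 against 446) and CCNE2 (955 against 569). G2/M and mitosis genes had negative ratios in 25 of 27 (exceptions BIRC5 and FOXM1), a median of -0.27 below all random lists and the largest ratio in CENPF (866 against 1646). None of either list reached 2-fold. The p53 targets had a median of -0.14 (0.33th percentile) and no change among 19.

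Mesenchymal genes had a median of -0.19 over 22 members, below all random lists, with falls of S100A4 and of the transcription factor TCF4 (2.74-fold, under 2-fold with the mean over probe sets). Matrix proteolysis and adhesion genes had a median of -0.15 (0.01th percentile) over 27, with 1 fall, the collagen receptor subunit ITGA2 (2.35-fold), and PLAU at 2621 against 3948. Among 23 inflammatory and NF-kB genes (median -0.05, 9.89th percentile, but -0.08 at the 2.37th under quantile normalization and the 1.87th with the 25th percentile floor), the neutrophil chemokines CXCL1 (2.56-fold) and CXCL2 (2.44-fold) fell and CCL5 rose 2.04-fold. The epithelial list (19 measured, median 0.05, 68.6th percentile), Wnt targets (11 measured, median 0.14, 97.0th percentile, 99.6th and 23.4th with the 25th and 65th percentile floors), alveolar type II markers (10 measured, median 0.06, 69.2th percentile) and immune and endothelial markers (5 measured, median 0.00, 32.2th percentile) had no 2-fold change. The fibroblast list had 2 measured members, THY1 (0.05) and COL1A1 (0.03), and no median was taken.

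**Figure D3:**
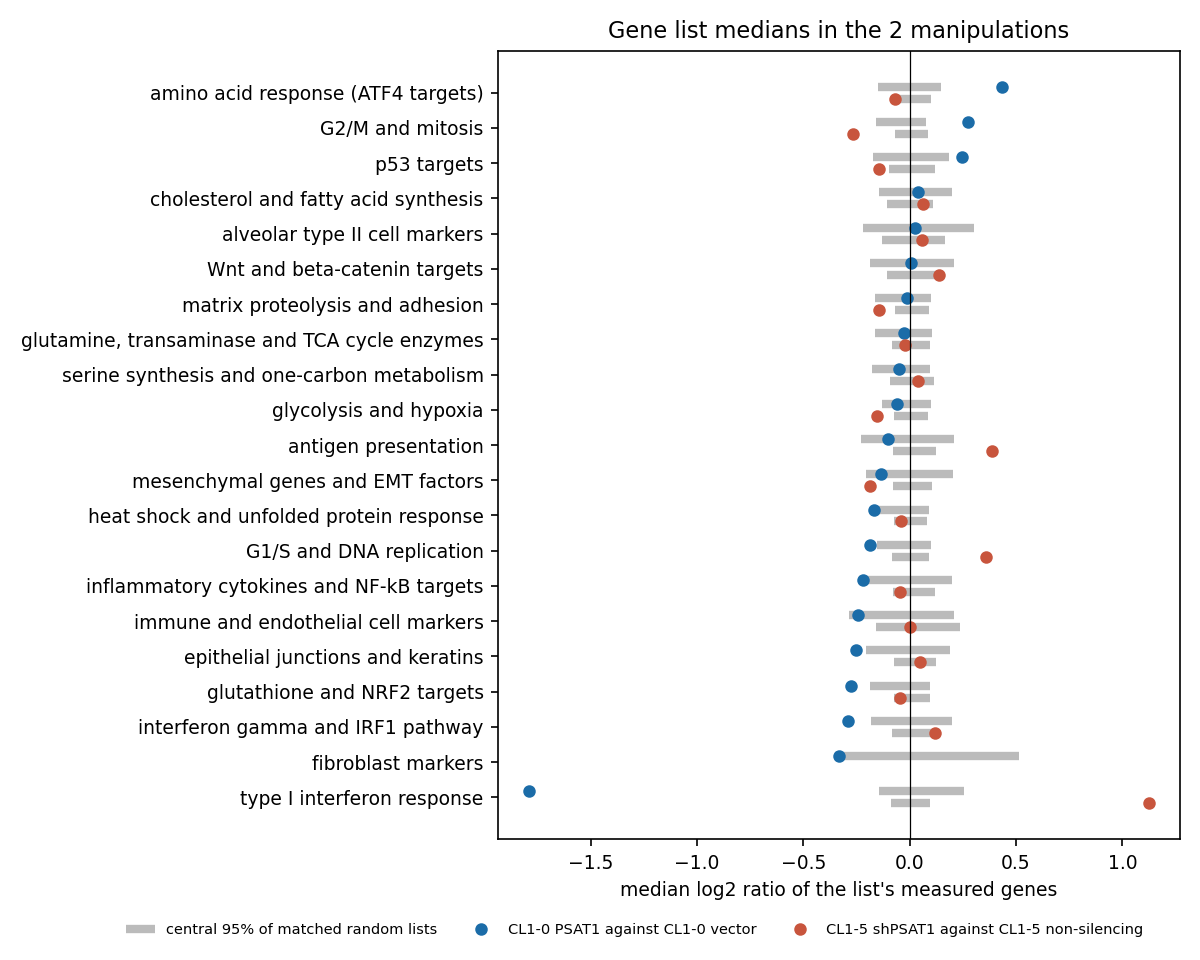
Median log2 ratio (horizontal axis) of each gene list fixed in advance, in CL1-0 with PSAT1 against vector (blue) and in CL1-5 with hairpin against non-silencing control (red), with grey bars for the central 95% of 10000 matched random lists. The type I interferon list lies at -1.79 and 1.12, outside the grey bars on opposite sides.

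The manipulations were set against each other gene by gene, since, per the labels, their constructs were meant to change PSAT1 in opposite directions, and they share no array. Genes that moved 2-fold in both moved mostly in opposite directions, and most of those were interferon-induced. Of 11941 genes measured in both pairs, 13 moved opposite ways, where lists of the same sizes drawn independently would share 0.815. Another 4 moved the same way, also above the 0.888 that independent lists would share. Both references treat genes as independent, which genes of one response are not. Outside the type I interferon list, the opposite genes were CCL5, CD24, H4C8, CDK19 and ORAI3. The 11 genes lower with PSAT1 and higher with the hairpin were RSAD2, CMPK2, IFIH1, ISG15, IFI6, IFIT1, IFIT2, IFIT3, CCL5, CD24 and H4C8, and 8 of the 13 belong to the type I interferon list. ISG15, a ubiquitin-like modifier, went from 8403 to 2379 with PSAT1 and from 2510 to 6968 with the hairpin. Higher with PSAT1 and lower with the hairpin were CDK19 (2.75-fold and 2.36-fold, both under 2-fold with the mean over probe sets), a kinase of the Mediator complex, and the calcium channel gene ORAI3. CD24 and H4C8 are measured by probe sets that can pick up related sequences. APOE and WASIR2 rose in both, and EFNA5 and NFKBIZ fell in both. These 4, with CD24, H4C8 and ORAI3, fall outside the rule for named genes.

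Across the 11273 genes above the floor on all 4 arrays, the log2 ratios of the manipulations correlated with Pearson r = -0.157 and Spearman rho = -0.171. Without the interferon lists, r was -0.141 over 11246 genes. These are correlations across genes, which are not independent replicates. A line contrast was made from the mean of the CL1-5 arrays minus the mean of the CL1-0 arrays. Array noise of equal size on both arrays of a line does not tie it to either manipulation. This contrast correlated with r = -0.156 with the CL1-0 manipulation and 0.0258 with the CL1-5 manipulation. It holds the manipulated arrays, so a change with PSAT1 enters it negatively and one with the hairpin positively, which can give these signs. With the control arrays alone, which each share an array with a manipulation, the correlations were 0.103 and -0.158.

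**Figure D4:**
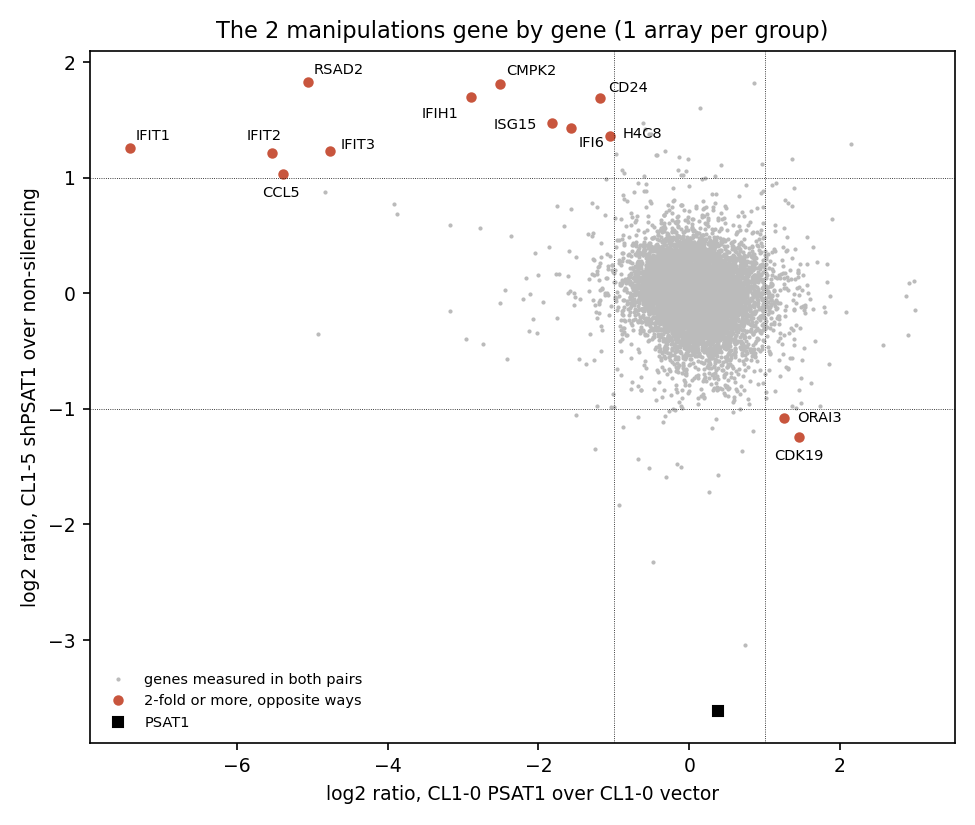
Log2 ratio in CL1-0 (horizontal axis, PSAT1 over vector) against log2 ratio in CL1-5 (vertical axis, hairpin over non-silencing control) for genes measured in both pairs, with dotted lines at 2-fold. The 13 genes that moved 2-fold in opposite ways are red, 11 of them at the upper left, and PSAT1 is the black square at 0.38 and -3.62.

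The control arrays of the lines were compared to describe the background on which each manipulation was made. The lines carry different vectors and are not known to be on a common scale, so line, vector and processing cannot be told apart. The median log2 ratio of CL1-5 over CL1-0 was -0.49 over 13720 measured genes, and log2 values of single genes and lists in this comparison are given relative to that shift, while 2-fold counts are on the deposited scale. CL1-5 had far more signal for some matrix-degrading and inflammatory genes and for calcium-binding S100A6 (16578 against 115, relative log2 7.66). The collagenase MMP1 (4508 against 18.1, at least 7.01), the urokinase PLAU (at least 6.82), the chemokine CXCL8 (at least 6.70) and the matrix protein TGFBI (at least 6.62) followed. CL1-0 had more of the gap junction protein GJA1 (10884 against 8.54, -7.31 at the bound), osteopontin, SPP1 (-7.29 at the bound), the stem cell transcription factor SOX2 (-7.01 at the bound) and ANXA1 (-6.81).

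On the deposited scale 720 genes were 2-fold higher in CL1-5 and 3402 lower. Quantile normalization gave 1291 and 1201, and median centring gave 1433 and 1193, so the excess of lower genes depends on the scaling. The other large rises were ARHGAP29 (at least 6.74), PRSS3 (at least 6.49), tissue factor, F3 (6.48), BEX1 (at least 6.42) and CDCP1 (6.30). Other large falls were ALDH1A1 (-6.72), ARID5B (-6.31), COL5A2 (-6.19), PRDX2 (-6.14), GASK1B (-5.97) and ID4 (-5.97), all at the bound. PSAT1 read 1760 against 4214, a relative log2 ratio of -0.77, and was under 2-fold with quantile normalization (-0.58). PHGDH had a relative ratio of -1.68.

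On the deposited scale, mesenchymal genes had 14 of 24 measured members higher in CL1-5 and 2 lower, TWIST1 and ZEB2, with a relative median of 2.28 above all random lists. Without multi-transcript probe sets the median before subtracting the shift was 0.27 in place of 1.79, still above all random lists. SNAI2 (at least 5.22), LOXL2 (at least 4.74, probe sets of opposite sign) and ITGB3 (at least 3.87) had the largest values after TGFBI. All of these are bounds, so their order follows the CL1-5 signal alone. Matrix proteolysis and adhesion genes had 13 rises and 5 falls among 28 (relative median 1.05, above all random lists), with CD44 at least 6.28 and the growth factor CCN2 at -5.38. Besides CCN2, the falls were CCN1, ITGAV, ADAM9 and ADAM10. Inflammatory and NF-kB genes had 9 rises among 23 and 2 falls, CCL5 and SOD2 (relative median 1.22, above all random lists), with IL1A at least 5.04, CXCL1 at least 4.70 and CXCL2 at least 4.43. Glycolysis and hypoxia genes had 6 rises and 2 falls among 27 (relative median 0.66, above all random lists). In that list NDRG1 (4.84) and ENO2 (at least 3.62) rose and ADM (-3.65) and SLC2A3 (-3.03) fell. The epithelial list had 3 rises, KRT8 (4.51), KRT18 (3.30) and CLDN4, and 3 falls, TJP1 (-1.11), OCLN (-0.85) and PKP2, with a relative median of 0.42 (96.5th percentile). This was 0.18 at the 86.65th under quantile normalization, the 99.5th under centring and the 98.1th and 99.6th with the 25th and 65th percentile floors. Under quantile normalization and centring the epithelial list had 6 and 7 rises and 0 falls, glycolysis and hypoxia 13 and 11 rises with 2 falls, inflammatory genes 14 rises with 2 falls in each, and matrix genes 14 and 15 rises with 2 falls.

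Type I interferon genes split between the control arrays of the lines. Of 29 measured members, 9 were higher in CL1-5 and 11 lower, but 12 and 10 under quantile normalization and 12 and 9 under median centring. OAS3 (622 against 63.6, relative log2 3.78) was higher, while RSAD2 (-4.14), IFI44 (-2.94) and IFIT1 (969 against 8422, -2.63) were lower. The named falls rest on the CL1-0 vector array. On the CL1-0 PSAT1 array RSAD2 (17.9), IFI44 (11.8) and IFIT1 (24.1) were below the floor. So were CCL5 and CXCL10, also lower on the CL1-5 control array. OAS3 read 56.7 there, still under its CL1-5 signal. The relative median was 0.53 (99.97th percentile on the deposited scale). It lay inside the central 95% of random lists under quantile normalization (95.2th percentile), median centring (93.6th), the 65th percentile floor (87.0th) and without multi-transcript probe sets (75.3th). The interferon gamma and IRF1 list had 5 rises and 3 falls among 21 and a relative median of 0.63 (99.95th percentile), and 8 rises and 1 fall under both other scalings. The rises were CD274 (at least 3.45), PSMB8 (at least 3.38), ICAM1 (2.52, probe sets of opposite sign), GBP3 and APOL6, and the falls were CXCL10 (-1.58), PSMB10 and IFNGR1 (-0.73). IRF1 was at -0.28 and IFNGR2 at 0.34. Antigen presentation genes had no 2-fold difference among 13 and a relative median of 0.42 (98.4th percentile), which was at the 96.8th with the 25th percentile floor and the 96.5th without multi-transcript probe sets. Both other scalings gave 1 rise.

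Serine synthesis and one-carbon genes were lower in CL1-5 in 8 of 18 members, with a relative median of -0.47 (1.5th percentile), but in 2 under both quantile normalization and median centring. Without multi-transcript probe sets the median lay at the 6.97th percentile. GLDC (-3.06) and PHGDH (-1.68) fell most, and PSPH and SHMT2 were at -0.46 and -0.57. The amino acid response list had 12 falls and 1 rise, VLDLR, among 27 (relative median -0.38, 6.24th percentile, and 1.91th with the mean over probe sets), against 4 falls and 3 rises under quantile normalization and 5 and 2 under centring, with the cystine transporter SLC7A11 at -2.43, ATF3 at -2.15 and asparagine synthetase ASNS at -1.91. Glutamine, transaminase and TCA cycle genes had 1 rise, glutamine synthetase GLUL (2.14), and 6 falls among 24 (relative median -0.25, 39.1th percentile), led by SUCLA2 (-1.45), and 1 of each under both other scalings. Glutathione and NRF2 targets had 4 rises, malic enzyme ME1 (4.61), AKR1C1 (2.53, probe sets of opposite sign), AKR1C2 (1.97) and GCLM, and 2 falls, GSR (-1.76) and GPX4, with a relative median of 0.43 (99.99th percentile). Both other scalings gave 6 rises and 1 fall. Cholesterol and fatty acid genes had 8 falls among 20 (relative median -0.39, 12.2th percentile), led by HMGCS1 (-1.79), and 3 under both other scalings. Heat shock and unfolded protein genes had 9 falls among 24 (relative median -0.31, 14.96th percentile), led by XBP1 (-1.79). Quantile normalization gave that list 1 rise and 1 fall, and centring 1 rise and 2 falls.

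G1/S genes had 11 falls among 25 (relative median -0.40, 9.18th percentile), led by MCM6 (-1.23), but 2 under quantile normalization and 4 under centring. G2/M genes had 4 falls among 27, KIF23 (-0.78), DLGAP5 (-0.69), BUB1 (-0.56) and BIRC5 (-0.56), with a relative median of 0.29 (99.99th percentile, and 94.3th without multi-transcript probe sets). Their direction turned under quantile normalization, with 6 rises and 0 falls, and under centring, with 4 rises and 0 falls. The p53 targets had 2 rises, GADD45A (3.39) and CDKN1A (3.14), and 4 falls, MDM2 (-1.63, probe sets of opposite sign), AEN (-1.16), RRM2B and SESN1, among 19 (relative median 0.42, 99.7th percentile), against 3 rises and 1 fall under quantile normalization and 3 and 2 under centring. Wnt targets had 1 rise, TNFRSF19 (2.24), and 3 falls, DKK1 (-1.28), AXIN2 (-0.82 at the bound, positive under both other scalings) and NKD1 (-0.56 at the bound), among 13 (relative median -0.15, 7.77th percentile). Wnt targets had 2 rises and 1 fall under quantile normalization and 1 of each under centring. Alveolar type II markers had 1 rise among 11, HOPX (at least 1.87), and a relative median of 0.25 (61.3th percentile). Fibroblast markers had 2 falls among 5, POSTN (-4.97) and COL3A1 (-2.19), both at the bound, and a relative median of 0.17 (58.7th percentile). Immune and endothelial markers had 1 rise among 5, PECAM1 (1.59), and a relative median of 0.54 (82.7th percentile).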

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

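The tests of scaling on the interferon lists, of constructs, of PSAT1 probe position, and of genomic DNA were chosen only after the result was seen, and the other tests in this part were set before.

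Probe sets without a gene name, which no comparison in the report uses, were counted by the same 2-fold rule. Of 3752 measured in CL1-0, 185 were higher with PSAT1 and 14 lower. Of 2797 measured in CL1-5, 2 were higher with the hairpin and 10 lower. The CL1-0 excess of rises was smaller under other scalings. Quantile normalization left 106 higher and 15 lower of 3490 measured, and median centring 116 and 16 of 3010. Another scaling can remove real rises as well as scaling error, so the part of the excess due to scaling is not known. As the whole cause, scaling is argued against by the ratio of higher to lower, 13.2 as deposited and 7.07 after quantile normalization. Noise of dim probe sets is argued against by a ratio of 8.25 among those whose brighter array reached the pooled 75th percentile. Genomic DNA in the labelled sample, if it raised all probe sets alike, would also raise 191 probe sets of olfactory receptors, taste receptors and keratin-associated proteins. The 95th percentile of their rise was 1.83 signal units, against a median rise of 99.4 units for the 185. The 185 were chosen for their rise, and whether genomic DNA adds signal evenly was not tested. An uneven contribution of genomic DNA therefore stays open. An earlier form of that test, a ratio without a floor, was dropped after it was seen, because near background it excludes nothing. What transcripts these probe sets read stays open, as does an effect of PSAT1, and many such probe sets may read introns or unspliced RNA, which was not tested.

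Type I interferon genes moved in opposite directions in the manipulations. Over the scaling, floor and probe set settings, the list's median stayed outside the central 95% of random lists by at least 0.353 in CL1-0 and 0.819 in CL1-5. Rescaling moves the list and its random lists much alike, so the scaling settings could hardly close this gap. A first bound of 0.5 on the CL1-0 median was passed only narrowly, at -0.52, and this form of the test was chosen after that. Other probe sets of the same genes had median ratios of -2.01 in CL1-0 (10 probe sets of 8 genes, 9 negative) and 0.686 in CL1-5 (14 of 12 genes, all positive), which argues against single faulty probe sets. A response to the vector or hairpin itself, or a control culture with an interferon response of its own, cannot be told apart from an effect of PSAT1, because each group has 1 construct and 1 array.

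The PSAT1 log2 ratio was only 0.38 on the array labelled as carrying the PSAT1 vector. Probe sets that lie outside the introduced sequence, or a vector that adds little to the endogenous level, could each give such a ratio, and these cannot be told apart without the probe and vector sequences. Saturation of the PSAT1 probes stays open, since the level at which a probe saturates is its own and no higher level of these probe sets was measured.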

How the results depend on the processing

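Each named result was recomputed under the alternatives. All alternatives in this part were planned, and the lists chosen after the data were seen are given elsewhere. No paired analysis was possible because each group has 1 array. Of 1777 recomputed values for 319 named gene ratios, 1685 kept their side of 2-fold, 74 fell below it, 15 rose above it and 3 reversed. Only a ratio first at 2-fold counts as reversed, and sign changes of ratios under 2-fold were not counted. Of 366 recomputed list medians for 62 results, 261 moved by less than 1 SD of random lists, 92 moved by more and 13 reversed, all in the comparison of the lines. Here only a median first outside the central 95% of random lists counts as reversed. Of those first inside it, 14 of 69 values changed sign in CL1-0, 4 of 71 in CL1-5 and 7 of 58 between the lines. What depth limits here is signal over background, since a fold against the floor is a bound and lists with few measured members rest on the floor chosen.

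Other scalings cut the differences between the lines from 4122 genes to 2492 (quantile) and 2626 (centring). Before subtracting the shift, PSAT1's log2 ratio between the lines went from -1.26 to -0.58 and -0.64. The median of all genes went from -0.49 to 0.00 and 0.09 in the same order. A 1.5-fold rule gave 1749 genes in CL1-0, 490 in CL1-5, 7271 between the lines and 87 moving opposite ways, and a 3-fold rule gave 114, 20, 1659 and 3. These follow from the rule's size. The second PSAT1 probe set gave -1.84 in CL1-5 and, before subtracting the shift, -1.98 between the lines. The line contrast that shares an array with each manipulation gave 0.103 in CL1-0 and -0.158 in CL1-5, where shared noise adds covariance by construction, and both changed sign (from -0.156 and 0.0258). The count of genes moving opposite ways ran from 9 (mean over probe sets, all 9 among the 13) to 16 (quantile normalization and the 25th percentile floor, each with all 13) under the other settings.

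The type I interferon median in CL1-5 was 1.21 under quantile normalization, 1.03 under centring, 0.999 with the 25th and 0.91 with the 65th percentile floor, 0.997 as the mean over probe sets and 1.21 without multi-transcript probe sets. In CL1-0 it was -0.52 with the 25th percentile floor and -2.51 without multi-transcript probe sets. Between the lines, before subtracting the shift, medians turned positive under quantile normalization and centring for glutathione and NRF2 targets (0.61 and 0.56), antigen presentation (0.53 and 0.51), G2/M (0.48 and 0.42) and p53 targets (0.37 and 0.48), as did the AXIN2 ratio (0.058 and 0.36) and the medians, first inside the random range, of epithelial genes (0.18 and 0.50) and alveolar type II markers (0.39 and 0.33). Centring alone turned fibroblast markers (0.19) and Wnt targets (0.02). Values also turned positive with the 25th percentile floor for glutathione and NRF2 targets (0.11), with the 65th for epithelial genes (0.14), and without multi-transcript probe sets for antigen presentation (0.19), p53 targets (0.038) and IDH2 (0.46). The type I interferon median between the lines turned negative, -0.39, both with the 65th percentile floor and without multi-transcript probe sets. The scaling reversals follow from the shift of all genes, and for the others the cause was not tested.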

Other observations

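The gene lists and the test in this part were all chosen only after the results were seen, and all are described on the data in which they were noticed.

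Ribosome biogenesis genes, which make and assemble ribosomal subunits, shifted by small amounts in opposite directions. In CL1-0 with PSAT1, 35 of 36 measured members had negative ratios (NOL8 was the exception), with a median of -0.45 below all 10000 random lists. In CL1-5 with the hairpin, 33 of 36 had positive ratios (UTP3, UTP20 and UTP23 were the exceptions), with a median of 0.16 above all random lists. No member reached 2-fold in either pair. Replication-dependent histone genes had a median of -0.58 in CL1-0, with 24 of 25 ratios negative (H2BC21 was the exception) and 3 genes lower, H2AC16, H4C8 and H2AC14. In CL1-5 their median was 0.18, with 4 genes higher, H4C8, H2BC5, H2BC11 and H2BC6. Histone genes share sequence between near-identical copies, so the values of single members are uncertain.

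Ciliary genes, which build and service the primary cilium, had positive ratios in 20 of 25 measured members in CL1-0 with PSAT1 (exceptions IFT43, IFT56, IFT57, IFT140 and TTC8), with a median of 0.42 at the 99.99th percentile. In CL1-5 their median was -0.05 (12.97th percentile), and no member reached 2-fold in either pair. Metallothioneins, small proteins that bind zinc and copper, had a median of 0.66 over 7 genes in CL1-0 (99.98th percentile) and 0.01 in CL1-5 (46.4th percentile), again with none at 2-fold. MT2A read 3317 with PSAT1 against 1702 with vector. Between the lines 6 of 7 metallothioneins were higher in CL1-5 and MT3 was the exception, with a relative median of 3.04. Their probe sets also share sequence between copies.

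IFNB1, the gene of interferon beta, read 81.9 on the CL1-0 vector array and lay below the floor on the other arrays (14.97, 14.98 and 14.6). The signal of 81.9 is itself less than 2-fold above the floor of 49.0, so IFNB1 does not count as lower with PSAT1. In the CL1-0 pair, genes that the transcription factor IRF3 can induce directly had a median of -3.90, with 13 of 14 lower, while genes that need interferon receptor signalling had a median of -0.17 over the 5 measured of 16, with 1 lower, PARP14. In the CL1-5 pair the medians were 1.22 (8 of 13 higher) and 0.97 (7 of 14 higher), a difference of 0.244. The hypothesis tested was that IRF3-direct genes moved in CL1-0 and receptor-dependent genes in CL1-5. It needs an IRF3 median further below in CL1-0, where the difference was -3.73, and a receptor median at least as far from 0 in CL1-5, which was not met. The lists were also made from genes seen to move, and most receptor-dependent genes were at the floor on both CL1-0 arrays, so the test decides nothing and the hypothesis stays open.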
